A study of Mus musculus with 6 samples.

How the data were processed

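The samples were 4 CTCF immunoprecipitation libraries and 2 input samples from Hepa-1c1c7 mouse hepatoma cells. Per the labels' protocols, chromium-treated cells received potassium chromate for 90 min before formaldehyde fixation, chromatin was sheared by sonication, and libraries were read from a single end on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the sample titles. Each CTCF library has a peak list, and no values of the input samples were used here. Per the submitters' processing notes, the tools were Bowtie and MACS2 and the build was mm10. Versions, thresholds, duplicate handling and filters are not given in the sources used here. The peak names in the deposited lists show that each library was called by itself, the number 1 libraries against input 1 and the number 2 libraries against input 2, so replicates were not pooled. The replicate number is therefore also the number of the shared input.

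Each deposited list gives a position and a score per peak. The score is a value of the authors' peak caller whose scale is not given in the sources used here, and the lowest score was just above 2 in each list. It was used to describe, rank or filter the peaks of a list. Counts of scores over 10 describe each list, and a floor common to the lists was applied only as an alternative, since sizes of scores may not be comparable between lists. Read totals are not given in the sources used here, so the depth is not known. The number of peaks, from 1905 to 14881, does not measure it. Binomial intervals cover counting error over peaks only, and peaks are not independent replicates.

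Positions were read into 1-based coordinates of mm10, and chromosomes 1 to 19, X and Y were used. Peaks of different lists were matched when they overlapped by at least 1 bp, and connected groups of matched peaks from different lists were merged into sites. Gene positions came from RefSeq gene records of the GRCm38.p6 assembly, which has the same coordinates as mm10, with 21887 protein-coding genes. These records give no strand here, so the start of transcription could not be placed. The planned measure, a peak midpoint within 1 kb of a transcription start, was replaced by a midpoint within 1 kb of either end of a protein-coding gene. This measure mixes promoters with the 3' ends of genes. The planned test of the CTCF motif needs the genome sequence and was not run.

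The background of each overlap and of each gene-end share was measured by moving every peak of a list at random by 20 to 200 kb in either direction, in 100 seeded draws, which keeps the regional density of peaks. Shares have exact Clopper-Pearson 95% intervals. Groups were compared with two-sided exact permutation tests over the 4 libraries, whose smallest p is 0.333. Odds ratios within a pair come from two-sided Fisher's exact tests, and those over pairs are Mantel-Haenszel odds ratios with an exact conditional test within 5 strata of the score rank. Paired recovery was tested with the exact McNemar test. Benjamini-Hochberg adjustment was applied within each family of tests. Gene lists were compared by Fisher's exact test against all other protein-coding genes with a gene-end peak in at least 1 library. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.

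The tests, the 12 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be chosen later. Fisher's exact tests of the gene-end share within each pair and the comparisons with shifted positions were not in that plan. The rule named the 8 genes with a lost site at a gene end with the highest mean within-list score percentile in the untreated libraries, up to 8 with a gained site by the percentile in the chromium libraries, up to 6 with a site in all 4 libraries, every listed gene lost or gained in both pairs, and up to 3 genes of each list with a site in all 4 libraries, of which there were 0. A site that this rule names is not reported here. Of the 274 listed genes, 270 matched a protein-coding gene and the remaining 4 are non-coding.

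The site merging and the stratified test were tested on simulated data. In lists of the real lengths, 32988 simulated peaks in all, 149 of 150 planted lost sites, 50 of 50 planted gained sites and 200 of 200 sites planted in all 4 lists were recovered, with 156 sites called lost and 52 called gained. In 100 simulations of the lost-peak odds ratio on 16202 peaks, the interval held a true value of 1 in 99 and a true value of 2 in 95. The simulated peaks were spread at random over the chromosomes, without the crowding of the real peaks. The simulation therefore does not measure how many chance matches the real lists hold. The odds ratio simulation drew peaks independently, so it does not cover error from clustered peaks. It also gave pair 2 a larger share of matched peaks than the data, where 41 of 4495 untreated 2 peaks were matched. No true value below 1 was simulated, so coverage in the setting of the real values was not checked.

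Alternatives were the stronger peaks of each list by score, a score floor of 3.75 common to all lists, lists of equal length (the 1905 with the highest scores), all sequences in the lists, a reciprocal overlap, peaks within 500 bp counted as shared, windows of 500 bp and 2.5 kb, any overlap of the peak with the window, no score strata, a replicate block, and each replicate pair left out. Further alternatives chosen after seeing the data left out windows of 100 kb with a score over 100 in any list, left out single libraries, took the excess over shifted positions in place of the gene-end share, and used another background for the gene lists.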

Results

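CTCF is a zinc finger protein that binds DNA at insulators, domain boundaries and many promoters. Its positions were mapped by chromatin immunoprecipitation and sequencing in Hepa-1c1c7, a mouse hepatoma cell line, without treatment and after 90 min with 25 µM potassium chromate, a hexavalent chromium salt. The series asks whether chromium changes the occupancy of CTCF sites, in particular those in promoters. There were 2 untreated and 2 chromium CTCF libraries, numbered 1 and 2 in each group, and 2 input samples, which were not analysed here beyond their role in the authors' peak calls. The input titles name no chromium treatment, so whether an input matched the chromium-treated chromatin is not known. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so a spread between them may be technical. The data are 4 lists of peaks called per library against an input, on genome build mm10. The number of reads behind each list is not given in the sources used here.

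On chromosomes 1 to 19, X and Y the lists held 11707 peaks in untreated 1, 14881 in chromium 1, 4495 in untreated 2 and 1905 in chromium 2. Chromium 1 had more peaks than untreated 1 by 0.35 on the log2 scale, while chromium 2 had fewer than untreated 2, a log2 difference of -1.24. The mean number was 8101 ± 5100 (SD, n = 2) in untreated and 8393 ± 9175 (SD, n = 2) in chromium libraries, and the difference in mean log2 number was -0.45 (two-sided exact permutation test, p = 1). With 2 libraries against 2 the smallest p this test can give is 0.333. Most peaks were narrow, and most scores lay low in the range of their list. The median width was 227, 225, 229 and 215 bp in untreated 1, chromium 1, untreated 2 and chromium 2, and the shortest width, 209 bp, was that of 35.4%, 38.3%, 32.1% and 46.1% of their peaks. The score of each peak is the authors' own value and serves here to describe, rank or filter peaks. Its median lay between 4.15 in chromium 2 and 4.50 in untreated 1, and scores over 10 were given to 240 peaks in untreated 1, 206 in chromium 1, 41 in untreated 2 and 5 in chromium 2.

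A group of 220 CTCF sites was called in both untreated libraries and chromium 1 but not in chromium 2. Sites at the ends of Nipsnap2, of Vps18 (a subunit of the endosomal tethering complexes), of Rapgef1 (an exchange factor for Rap1), of Kdm3b (a histone H3K9 demethylase), of Atp5g2 (a subunit of the mitochondrial ATP synthase), of Slc48a1 (a heme transporter) and between the neighbouring genes Cd63 and Rdh5 had the highest scores near genes in this group, with mean within-list score percentiles of 98.1 to 99.8. These genes were chosen after their values were seen, as the 8 with the highest mean percentile among the sites of that pattern, of which 53 lay within 1 kb of a gene end. The Nipsnap2 site spanned 129724737 to 129725216 on chromosome 5, next to the lower-coordinate end of the gene, and the Kdm3b site 34776722 to 34777083 on chromosome 18. Only 15 sites were found in all 4 lists. Of these, 2 lay at gene ends. The first was at Sh3glb1, which encodes endophilin B1 (chromosome 3, 144720302 to 144720943), at percentiles of 99.8, 99.97, 99.8 and 57.6 in untreated 1, chromium 1, untreated 2 and chromium 2. The second was at Snai1, a transcription factor of epithelial-mesenchymal transition (chromosome 2, 167537818 to 167538251), at 99.7, 93.3, 67.8 and 64.5 in the same order.

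Most peaks were nevertheless found in a single list. The 4 lists merged into 31285 sites, of which 1425, or 4.55%, were found in 2 or more lists and 248 in 3 or 4. Of the peaks of untreated 2, 436 (9.70%, exact 95% interval 8.85 to 10.6) overlapped untreated 1 and 371 (8.25%, 7.47 to 9.10) overlapped chromium 1. Untreated 1 and chromium 1 shared 1020 peaks, 8.71% of untreated 1 (8.21 to 9.24). Chromium 2 overlapped less, with 59 of its peaks in untreated 1 (3.10%, 2.37 to 3.98), 40 in chromium 1 (2.10%, 1.504 to 2.85) and 41 in untreated 2 (2.15%, 1.55 to 2.91). Each count was above that for peaks moved at random by 20 to 200 kb, whose mean over 100 draws was 102 for untreated 1 and chromium 1, 40.0 for the 2 untreated libraries and 18.1 for the 2 chromium libraries. The excess was 10.9-fold between the untreated libraries, 10.0-fold in pair 1, 7.85-fold between chromium 1 and untreated 2, 5.33-fold in pair 2, 4.03-fold between untreated 1 and chromium 2 and 2.21-fold between the chromium libraries. The lists therefore did not group by treatment. The Jaccard index, the share of merged sites held by both lists of a pair, was 3.99% for untreated 1 with chromium 1, 2.76% for the untreated libraries and 0.245% for the chromium libraries.

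**Figure D1:**
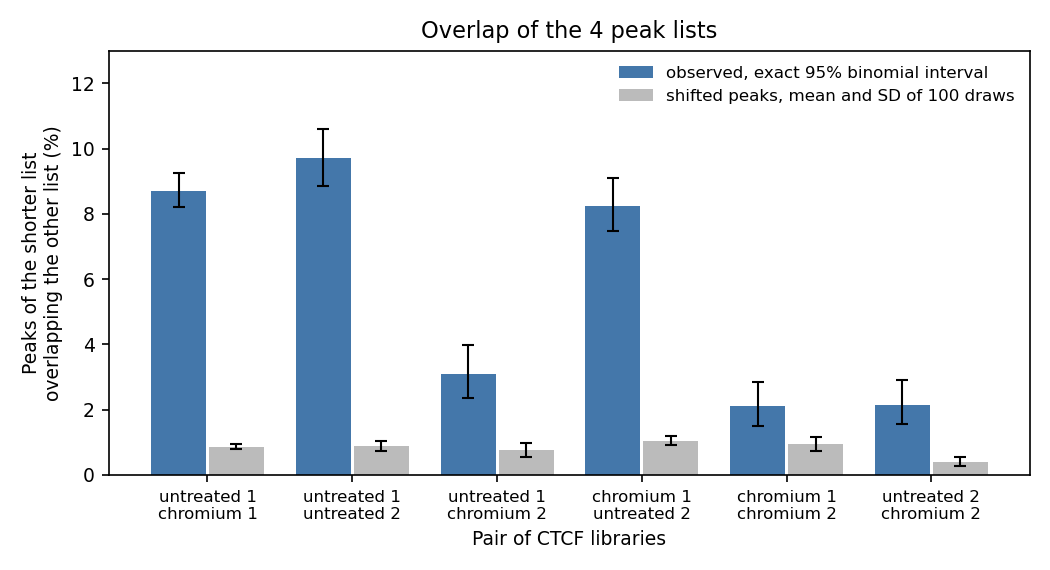
Peaks of the shorter list of each pair that overlap the other list by at least 1 bp, in percent (blue bars, with exact 95% binomial intervals), beside the same peaks moved at random by 20 to 200 kb (grey bars, mean and SD of 100 draws). The 3 pairs among untreated 1, chromium 1 and untreated 2 lie between 8.25% and 9.70%, and the 3 pairs with chromium 2 between 2.10% and 3.10%.

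The 4 lists shared a skew between chromosomes. Chromosome 15 held 13.3% of the peaks of untreated 1, 12.99% of chromium 1, 22.0% of untreated 2 and 24.7% of chromium 2, while chromosome 12, which is longer, held 0.376%, 0.376%, 0.2002% and 0.0525% in the same order. Chromosomes 17 and 18 were also rich in peaks, with 10.8 and 9.47 peaks per Mb in untreated 1 against 0.367 on chromosome 12 and 0.275 on chromosome X.

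**Figure D2:**
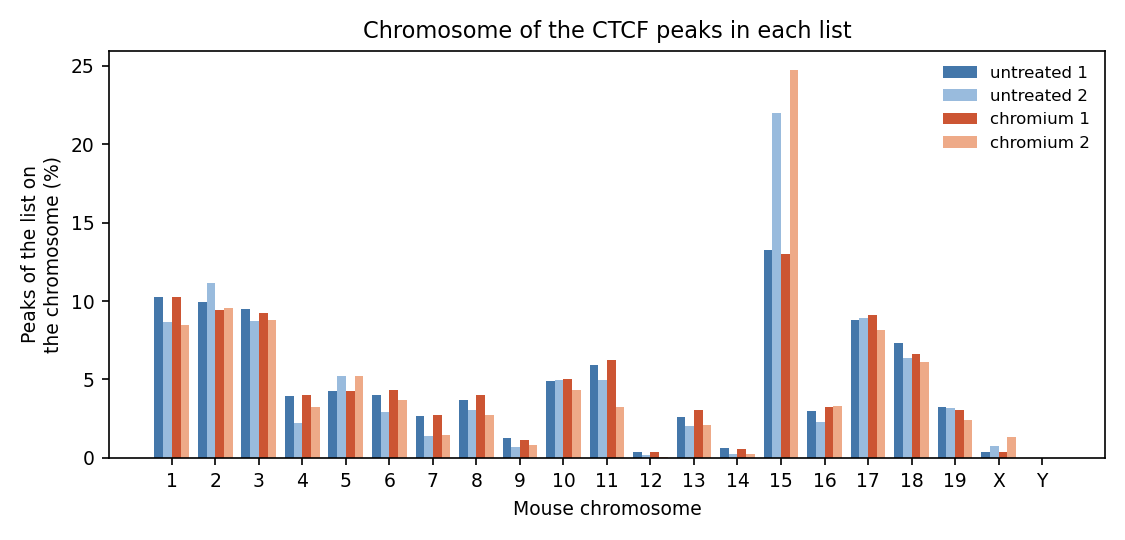
Percent of the peaks of each CTCF library on each mouse chromosome, with a bar for each library (blue for untreated, orange for chromium). Chromosome 15 holds between 12.99% and 24.7% of a list, and chromosomes 12 and 14 under 1% in each.

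The comparison by treatment asks which CTCF sites were called in both untreated libraries and in neither chromium library, here termed lost, and which showed the opposite pattern, here termed gained. There were 198 lost and 15 gained sites. At shifted positions the overlaps averaged 40.0 between the untreated lists and 18.1 between the chromium lists, with highest values of 55 and 30. The 15 gained sites are thus no more than random placement gives, and chance overlaps may also be among the lost sites. Lost sites at gene ends with high untreated scores lay between Cox14, a cytochrome c oxidase assembly factor, and Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase (chromosome 15, 99725318 to 99725667, mean percentile 96.1), between Bola2 and Slx1b, which encodes the catalytic subunit of a structure-specific endonuclease (chromosome 7, 126695581 to 126696076, 95.8), at Paxbp1 (chromosome 16, 91044467 to 91044839, 94.6), and at Plin3, a lipid droplet coat protein (chromosome 17, 56291205 to 56291479, 93.9). The Cox14 site had a separate chromium 1 peak centred 0.807 kb away. The nearest chromium 1 peak was 3.48 kb from the Paxbp1 site and at least 13.5 kb from the Bola2 and Plin3 sites. In all, 38 lost sites lay at the ends of 45 genes. The gained sites included 1 at gene ends, inside Slc30a7, a zinc transporter, 568 bp from its end and 603 bp from that of the neighbouring Extl2, a glycosyltransferase (chromosome 3, 116006684 to 116007009, mean percentile 90.4 in the chromium libraries).

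Of the 435 sites called in both untreated libraries, 235 (54.0%) were also called in chromium 1 and 17 (3.91%) in chromium 2, so that 198 (45.5%) were called in neither. Loss in chromium 1 and loss in chromium 2 went together, with an odds ratio of 6.51 (95% interval 1.32 to 32.2) within 5 strata of the untreated score rank (two-sided exact conditional test, p = 0.0141). That relation rested on the 17 sites found in chromium 2 and was not past 0.05 among the stronger peaks, at 1.57 (exact p = 0.724) in the list of peaks at or above each list's median score and 2.07 (exact p = 0.377) above a common score floor. Absence also went together between lists that differ in treatment. Of the sites in untreated 1 and chromium 1, 15 were in both number 2 lists and 774 in neither. A further 220 were in untreated 2 but not chromium 2, and 10 in chromium 2 but not untreated 2. The relation therefore cannot separate loss under chromium from sites that recur more or less often in any list. The other ways to split the 4 libraries into pairs gave 774 sites only in untreated 1 and chromium 1 with 23 only in untreated 2 and chromium 2, and 33 only in untreated 1 and chromium 2 with 134 only in chromium 1 and untreated 2. The total by treatment, 213, was thus below the 797 of the split by replicate number and above the 167 of the crossed split, and 3 splits cannot give a share under 0.05. These raw totals grow with list length, and untreated 1 and chromium 1 are the longest lists. Relative to shifted positions, the overlap of that pair was 10.0-fold and that of the untreated libraries 10.9-fold. The count of lost sites depended mainly on chromium 1. It was 200 with chromium 2 left out and 418 with chromium 1 left out.

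Untreated 1 recovered the peaks of untreated 2 more often than chromium 1 did, although its list was shorter than that of chromium 1, in a test chosen after the data were seen. Of the untreated 2 peaks, 201 overlapped untreated 1 alone and 136 chromium 1 alone (two-sided exact McNemar test, p = 0.000472, adjusted p = 0.00063 over 4 such tests, Benjamini-Hochberg). Of the chromium 2 peaks, 35 overlapped untreated 1 alone and 16 chromium 1 alone (p = 0.011, adjusted p = 0.011, same exact test). With untreated 1 and chromium 1 at equal length the counts were 137 and 79 for untreated 2 peaks (exact p = 9.6e-05) but 15 and 9 for chromium 2 peaks (exact p = 0.307), which ended that call. Among the peaks of untreated 1, 419 overlapped untreated 2 alone and 42 chromium 2 alone (exact McNemar p = 2.9e-79, adjusted p = 1.16e-78), and with those lists at equal length the counts were 283 and 47 (exact p = 3.2e-42). At that length chromium 2 stayed whole and untreated 2 was cut to its strongest peaks. Peaks are not replicates, and these p-values compare the libraries, not the treatments.

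CTCF peaks at the ends of protein-coding genes made up a smaller share of the chromium list than of the untreated list in both pairs. Within 1 kb of either end of a gene lay 862 peaks (7.36%, exact 95% interval 6.90 to 7.85) in untreated 1, 888 (5.97%, 5.59 to 6.36) in chromium 1, 322 (7.16%, 6.43 to 7.96) in untreated 2 and 82 (4.30%, 3.44 to 5.32) in chromium 2. At shifted positions the share was 4.73%, 4.48%, 4.64% and 3.71% in the same order, so that the excess was 2.63, 1.48, 2.52 and 0.60 percentage points. The difference, chromium minus untreated, was -1.40 points in pair 1 (Fisher's exact test, p = 5.7e-06, adjusted p = 1.1e-05) and -2.86 points in pair 2 (Fisher's exact test, p = 1.1e-05, adjusted p = 1.1e-05). These tests within pairs were not planned beforehand, and peaks are not replicates. Across libraries the mean was 7.26% ± 0.141 (SD, n = 2) for untreated and 5.14% ± 1.18 (SD, n = 2) for chromium, a difference of -2.13 points in which both chromium values lay below both untreated ones (two-sided exact permutation test, p = 0.333, the smallest it can give). With lists of equal length the difference kept its sign in both pairs, but chromium 1, at 10.2%, lay above untreated 2, at 7.82% (exact permutation p = 0.667). Peaks inside genes but away from their ends were 42.6% of untreated 1, 44.1% of chromium 1, 41.6% of untreated 2 and 41.3% of chromium 2, and peaks outside genes and away from their ends were 50.0%, 49.9%, 51.2% and 54.4% in the same order.

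**Figure D3:**
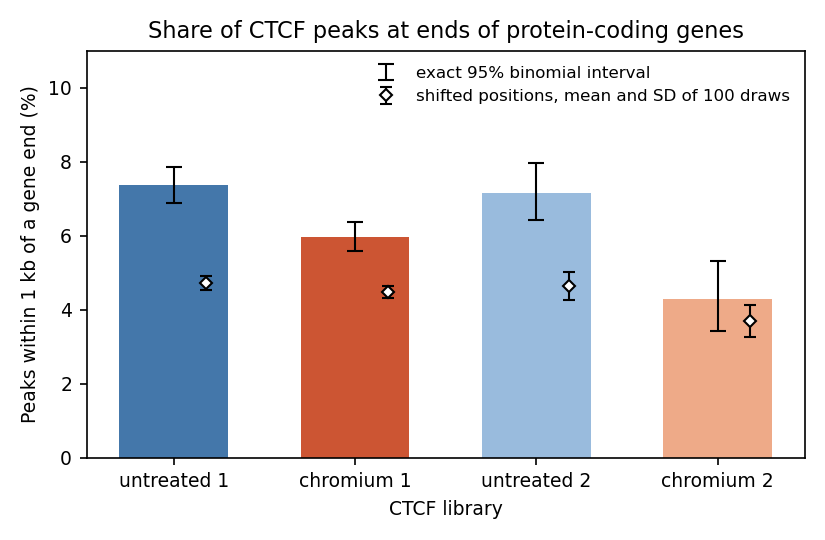
Share of the peaks of each CTCF library whose midpoint lies within 1 kb of either end of a protein-coding gene, in percent (bars, with exact 95% binomial intervals), and the share of the same peaks moved at random by 20 to 200 kb (open diamonds, mean and SD of 100 draws). The chromium bars, 5.97% and 4.30%, lie below the untreated bars, 7.36% and 7.16%.

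Peaks at gene ends were matched between the libraries of a pair more often than other peaks. In pair 1, 18.2% of the 1020 untreated peaks with an overlapping chromium peak lay at gene ends, against 6.33% of the 10687 without (odds ratio of the unmatched peaks 0.303, Fisher's exact test, p = 9.7e-34). In pair 2 the shares were 9.76% of 41 and 7.14% of 4454 (odds ratio 0.711, Fisher's exact test, p = 0.534). Over both pairs and within 5 strata of the score rank, the odds ratio was 0.397 (95% interval 0.330 to 0.478, exact conditional test, p = 2.3e-20). For chromium peaks without an untreated partner it was 0.271 (0.225 to 0.325, exact conditional test, p = 4.0e-37), with 5.05% of 13856 unmatched peaks at gene ends in pair 1 and 4.18% of 1864 in pair 2. Both stratified values rested on pair 1, since pair 2 alone gave 0.774 (exact p = 0.556) and 0.409 (exact p = 0.0991).

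A gene-end peak was called at 943 of 21887 protein-coding genes in untreated 1, 944 in chromium 1, 357 in untreated 2 and 94 in chromium 2. By gene, without asking that the peaks coincide, 60 genes had such a peak in both untreated libraries and in neither chromium library, 6 had the opposite pattern, 68 had one in all libraries but chromium 2, and 4 had one in all 4. Of 270 protein-coding genes in the 12 lists fixed beforehand, 36 had a gene-end peak in at least 1 library. Of these, 3 lost it in both pairs and 0 gained it, and with a window of 500 bp or of 2.5 kb Pds5b was the only gene to do so. The 3 were Pds5b, a regulator of cohesin, with peaks at 150673549 to 150673843 and 150673522 to 150673743 on chromosome 5 in untreated 1 and untreated 2, Apoa2, a liver apolipoprotein, with peaks near 171220920 on chromosome 1, and Actb, cytoplasmic beta-actin, whose untreated 1 and untreated 2 peaks lay at opposite ends of the gene. The score percentiles in untreated 1 and untreated 2 were 91.6 and 22.5 for Pds5b, 25.3 and 9.15 for Apoa2, and 18.3 and 37.3 for Actb.

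Among the hepatocyte genes, Apoa2 and Cebpb, a liver transcription factor, had gene-end peaks in both untreated libraries, and Tat, tyrosine aminotransferase, in untreated 2. Cebpb also had a peak in chromium 1, and none of the 3 had one in chromium 2. In the p53 and DNA damage list, Trp53 had peaks in untreated 1, chromium 1 and untreated 2, Mdm2 in untreated 1 and chromium 1, and Cdkn1a and Parp1 in chromium 1 alone. Among the immediate early and stress kinase genes, Dusp1, a MAP kinase phosphatase, was called in all libraries but chromium 2, Ddit3 in untreated 1, Ier3 in chromium 1 and Fosl1 in chromium 2. In the metal handling list, Mt1, a metallothionein, had a peak in untreated 1, and Mtf1, its transcriptional activator, Slc40a1, the iron exporter ferroportin, and Slc39a8, a zinc and manganese importer, had peaks in chromium 1. In the list of AHR and xenobiotic genes, Cyp1b1 was called in both number 1 libraries and Ugt1a6a in both number 2 libraries, with Gstm1 and Por in untreated 1 alone. Of the NRF2 genes, Gclm and Prdx1 were called in untreated 1 and Sqstm1 in chromium 1. Of 29 cell cycle genes, Ccna2, Ccnd1 and Cdk2 were called in untreated 1 and E2f1 in untreated 2, and the loss of the first 3 in pair 1 did not pass its test (Fisher's exact test, p = 0.136, adjusted p = 0.822, and p = 0.562 against genes with an untreated 1 peak alone). Besides Pds5b, the CTCF and cohesin list had Nipbl in untreated 2 and Nucks1 and Parp1 in chromium 1. The Hox list had Hoxc8 in untreated 2. No protein-coding gene of the list of imprinted and boundary loci, and none of the list for other cell types, had a gene-end peak in any library. Neither absence passed a test against all other protein-coding genes, chosen after the data were seen. Fisher's exact test gave p = 0.625 (adjusted p = 0.625) for the former list and p = 0.253 (adjusted p = 0.410) for the latter. The single genes above were named after their values were seen. Many of them were called in 1 list only. Peaks found in no other list lay at gene ends in 6.08% of cases in untreated 1, 4.96% in chromium 1, 5.44% in untreated 2 and 4.15% in chromium 2. At shifted positions the whole lists gave 4.73%, 4.48%, 4.64% and 3.71% in the same order. Many such calls are thus no more than random placement gives, and a call in 1 list only does not show gain or loss.

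No list passed the test for losing gene-end peaks more or less often than other genes with a peak. The 36 tests of loss in pair 1, pair 2 or both gave adjusted p-values of 0.218 or more (Fisher's exact test, Benjamini-Hochberg), and 1 of them was under 0.05 before adjustment, the hepatocyte genes in pair 2 (exact p = 0.00604). That background includes genes with no untreated 2 peak to lose. Against the genes with such a peak alone, a background chosen after the data were seen, the exact p for this list was 1, and the only test under 0.05 of the 36 was that of the AHR list in pair 2, where Ugt1a6a kept its peak (exact p = 0.042, adjusted p = 1). Of the 13 listed genes with an untreated 2 peak, Ugt1a6a was the only gene also called in chromium 2. Housekeeping genes stood out in another way. Of 15, 6 had a gene-end peak in at least 1 library (B2m, Rplp0, Actb, Gapdh, Rpl13a and Tbp), against 8.56% of all protein-coding genes (Fisher's exact test, p = 0.00099, adjusted p = 0.0119 over the 12 lists, a test chosen after the data were seen). Of the 6, only Actb was called in more than 1 list, and its peaks lay at opposite ends of the gene.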

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

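The untreated 2 list held 14 peaks on the mitochondrial genome, which entered only the alternative that took all sequences, while the other 3 lists held 0. They lay between positions 488 and 15175, covered 4609 bp and had scores of 5.91 to 44.1.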

How the results depend on the processing

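Alternatives that left out windows of extreme score or single libraries, the excess over shifted positions and the other list background were chosen after seeing the data. The lower gene-end share in chromium kept its sign under all 12 alternatives, from -1.40 to -3.54 points, but at equal list lengths the groups overlapped (exact permutation p = 0.667). Without 1 replicate pair it ran from -2.86 to -1.40 points. The ratio of mean Jaccard index within treatments to that between them was 0.86 and stayed between 0.85 and 0.91 in 5 alternatives. The replicate numbers mark a shared input and nothing else known. Over the 1425 sites in 2 or more lists, the presence of sites deviated together by number with a correlation of 0.267. Of these sites, 774 were found only in untreated 1 and chromium 1, the longest lists. An effect of the replicate number on this correlation therefore cannot be told apart from list length. With the replicate number as a block, the differences stayed at -0.45 for log2 peak number and -2.13 points for the gene-end share, with exact sign-flip p-values of 1 and 0.5, the latter the smallest possible. The log2 peak number without 1 pair ran from -1.24 to 0.35.

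Lost sites fell from 198 to 131 in the stronger part of each list and to 92 at equal lengths, as fewer peaks enter. Without 1 pair they ran from 4452 to 10685, since a single peak then suffices. They numbered 418 without chromium replicate 1 and 200 without chromium replicate 2. Gained sites numbered 5 in the stronger part, 7 above the common floor, 8 at equal lengths, 45 with peaks within 500 bp counted as shared, 25 and 16 without untreated replicate 1 and 2, and 1864 to 13852 without 1 pair. The odds ratio for agreement of loss was 1.57, 2.07 and 6.41 (exact p = 0.724, 0.377 and 0.119) in the stronger part, above the floor and at equal lengths, where fewer sites were tested. It was past 0.05 in the other 4 alternatives, from 4.33 to 12.5. The gene-end odds ratios kept direction and threshold in 11 of 12 alternatives each. For lost peaks they ran from 0.312 to 0.774 and for gained peaks from 0.207 to 0.409, with 0.387 to 0.774 and 0.267 to 0.409 when 1 pair was left out, pair 2 having 41 matched peaks. Listed genes lost in both pairs numbered 1 with a window of 500 bp and 1 with 2.5 kb. At equal lengths, chosen after seeing the data, the ratio of chromium 2 peaks in untreated 1 alone to those in chromium 1 alone was 1.67 (exact p = 0.307). No list passed its test under the 4 alternatives for gene lists. The motif alternatives were not run. Unknown read depth limits every statement on absent peaks.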

Other observations

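The tests in this part were chosen after the results were seen, except the gene-end share at equal list lengths, which was fixed before the data were examined. Fisher's exact test of that share in pair 1 was chosen later. Recurrent CTCF sites were most frequent on distal chromosome 2. Of the 248 sites found in 3 or 4 lists, 28 lay between 165 and 170 Mb of chromosome 2, while the next 5 Mb bin held 9. The stretch includes 5 of the 15 sites of all 4 lists, at Snai1, inside Ptgis (prostacyclin synthase), inside Atp9a and on both sides of Cebpb, at 167680002 to 167680482 and 167713351 to 167713682. The Cebpb gene itself had a gene-end site at 167688493 to 167688846 in both untreated libraries and chromium 1. Only 2 of the 28 sites lay at gene ends. By peaks found in 1 list only, this bin ranked 3 of 517 in untreated 1. Of the 15 gained sites, 1 (6.67%) lay at a gene end, against 5.97% of all chromium 1 peaks and 4.30% of all chromium 2 peaks. The others included sites inside Nf2, Ext1 and Dlgap1, in a set no larger than random placement gives. Of the non-coding genes in the fixed lists, Airn had a gene-end peak in untreated 1, and H19, Kcnq1ot1 and Meg3 had none in any library.

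Recurrence and gene ends went together in 3 of the libraries. Among peaks found in any other list, 18.0% lay at gene ends in untreated 1 (exact 95% interval 15.9 to 20.2), 17.7% in chromium 1 (15.6 to 20.0) and 18.5% in untreated 2 (15.4 to 21.8), against 7.07% in chromium 2 (2.89 to 14.0). Among peaks found in no other list the shares were 6.08%, 4.96%, 5.44% and 4.15%. Of the 435 sites of both untreated libraries, 19.2% of the 198 lost and 23.2% of the 237 others lay at gene ends (odds ratio 0.786, Fisher's exact test, p = 0.348). The highest scores of 3 lists fell in 2 windows of 100 kb, at 98600001 to 98700000 on chromosome 2 and 3000001 to 3100000 on chromosome 9, with scores of up to 2156 in untreated 1, 1546 in untreated 2 and 992 in chromium 2. The chromosome 9 window also held the highest chromium 1 score, 335.

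Peaks crowded on a few chromosomes in all 4 lists. The tables argue against gene density as the cause, since peaks found in 1 list only correlated with protein-coding genes over 517 bins of 5 Mb at a Spearman rho of at most 0.33. Such peaks followed the same regional density in lists called against different inputs, with a rho of at least 0.82, which is consistent with regional copy number or read density common to these cells, as a hypothesis. The step on chromosome 15, from 90 peaks of untreated 1 in the bin of 65 to 70 Mb to 11 in the next, has the form such a difference would give. No biological explanation was tested, and bins are not independent.

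The lower gene-end share in chromium was not accounted for by list length in pair 1, where with both lists at equal length the difference was -3.57 points, 13.8% against 10.2% (Fisher's exact test, p = 0.00083). In pair 2, where the difference was -3.52 points, the shortening leaves chromium 2 whole, so list length was not tested there and stays open. Regional placement of the peaks did not account for it either, as the smaller difference after subtracting shifted positions was -1.15 points. A weaker immunoprecipitation in the chromium libraries stays open and cannot be told apart from an effect of chromium. The share of peaks found in any other list was lower by -5.42 points in chromium, which either could give.

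Few sites of the other lists were found in chromium 2. Of the whole untreated 2 list 9.70% overlapped untreated 1, and of its 1905 strongest peaks 15.5%. Of the 1905 chromium 2 peaks 3.10% did (Fisher's exact test against the 1905 untreated 2 peaks, p = 2.3e-42). Dropping the weaker peaks thus raised the untreated 2 share, so shortening of that kind alone would not give the low share of chromium 2. The cut leaves chromium 2 whole, so shortening of other kinds was not tested and stays open. Chromium 1 recovered 0.85 times as many untreated 2 peaks as untreated 1 did, and chromium 2 recovered 0.14 times as many untreated 1 peaks as untreated 2 did, or 0.77 and 0.20 at equal list lengths. The value of 0.20 again sets the whole chromium 2 list against the strongest untreated 2 peaks. With 1 library behind each ratio, a chromium effect of equal size in both libraries cannot be told apart from an unequal effect or a poorer library, since the spread between libraries is unknown.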
